A study of Homo sapiens with 13 samples.

How the data were processed

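STARR-seq reads out enhancer activity by placing a candidate enhancer inside a reporter transcript, so that an active sequence raises its own share among the mRNA. MEC1 cells, an established line of chronic lymphocytic leukaemia (a B lymphocyte cancer), received libraries of designed arrays tagged with random 12 bp barcodes. For the episomal assay, RNA was taken 24 h after transfection, per the labels' protocols. The 5 bp and the 10 bp spacer library each had 1 plasmid DNA library and 2 mRNA libraries from duplicate transfections. For the integrated assay the 5 bp library was placed by CRE-mediated cassette exchange into a landing pad that carries GFP. Cells without GFP were sorted 10 to 12 days later and grown for another 6 to 7 days, per the labels' protocols. RNA and genomic DNA were then extracted jointly in triplicate, giving 3 mRNA and 3 genomic DNA samples beside 1 plasmid DNA sample. Nothing in the labels says that the triplicates came from separate cultures, so p-values for the integrated library measure the spread between these extractions, which may be technical. The 13 samples were grouped by the library, the spacer and the material named in their titles.

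For the episomal libraries the authors deposited raw read counts per barcode, per the file headers, with a construct name for each assigned barcode. Every listed barcode had at least 1 read in each of the 3 libraries of its table, so barcodes without mRNA were left out before deposit and the activity of weak constructs is overstated. For the integrated library the authors deposited values in RPM (reads scaled to the library total) per barcode for mRNA and genomic DNA, and whole-number counts for plasmid DNA. Each of its 16189 barcodes had at least 2 RPM in all 3 genomic DNA samples. The RPM values lay on a grid of equal steps, but the mRNA samples held too few low values to show that 1 step is 1 read, so no count test was run on them. The barcode counting, the aligner and their versions, the motif sequences and the position of the landing pad are not given in the sources used here. A further 9 columns of per-sample values matched no sample's labels and were not used.

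The episomal libraries held between 3850658 and 4563359 reads. Between 16.6% and 18.5% of these reads belonged to barcodes without a construct name, and these reads stayed out of library sizes and tests. Barcodes with at least 5 plasmid reads were kept, their reads were summed per construct, and constructs with at least 5 such barcodes entered the analysis. This left 236860 barcodes in 542 constructs (median 391 barcodes) for the 5 bp library and 210844 barcodes in 442 constructs (median 415) for the 10 bp library. The filters used plasmid DNA only. The 2 mRNA replicates of each library differed by more than sampling noise, with a chi-square of 6.41 and 6.76 per degree of freedom across constructs, and were treated as separate replicates. In the integrated library 513 constructs had at least 3 barcodes. PCR reads carry no molecular identifiers here, so read numbers overstate the number of independent molecules.

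The 442 designs present in both episomal libraries were fitted together over the 6 libraries with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, 4 groups) in R 4.3.3. The contrasts were mRNA against plasmid DNA in each library and the difference of these ratios between spacers. With 1 plasmid DNA library per spacer, the plasmid DNA was taken to vary like the mRNA libraries. The integrated library was fitted with limma 3.58.1 on log2(summed RPM + 0.5), mRNA against genomic DNA, so that folds of weak constructs are understated. Benjamini-Hochberg adjusted p-values under 0.05 passed. Per construct, the log2 ratio of its share of mRNA to its share of plasmid DNA (integrated: of summed mRNA RPM to genomic DNA RPM) was taken per replicate and is called activity. The 3 constructs named rd, 1 per context, carry none of the 8 motif names and were taken as constructs without a motif.

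Motif levels were compared by permuting motif labels within copy number and context. Copy number slopes were fitted by least squares with context as a term and tested by permuting copy numbers within context. Matched differences (flanking context, mixed against homotypic arrays, motif order) were tested by two-sided sign flips, exact for fewer than 10 values and otherwise with 100000 draws, as in the other permutation tests. The smallest p these draws can give is 1e-05. P-values were adjusted over the motifs or pairs and the 3 libraries: 24 motif levels, 24 slopes, 9 context differences, 84 pairs and 24 orders. The differences between spacers of homotypic arrays and the slopes of the share of integrated barcodes with mRNA were each adjusted over the 8 motifs alone. All these tests take constructs as units, and constructs are not biological replicates, so the tests concern these designs in these transfections. A mixed array was set against the copy-weighted mean of the log2 activities of its 2 homotypic arrays of equal total copy number and context. Mixed arrays of a pair with equal copy number and context share these homotypic arrays. Their differences are therefore not independent, which the sign flips ignore, so the p-values of pairs may be too small. The sign flip used the mean difference and the median is reported as the size, because on simulated data a sign flip of the median called 0% of true effects with 6 values. Analyses by motif used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Named constructs were chosen by a rule fixed before the data were examined: per comparison, the 5 largest increases and the 5 largest decreases past the threshold with the same direction in every replicate, and the 5 highest and 5 lowest motif pairs.

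The edgeR and limma fits and the permutation tests of motif levels, slopes and matched differences were tried on simulated data first. The contrast between spacers and the permutation test of correlations were not. For the 5 bp comparison over 442 designs, edgeR called 84% of simulated log2 changes of 0.25, 100% of 0.5 and 3.31% of unchanged designs. For the integrated comparison over 513 constructs, limma called 78% of log2 changes of 1, 100% of 2 and 2.24% of unchanged constructs. The edgeR simulation gave plasmid DNA the same spread as mRNA, so it could not check that assumption. The limma simulation used normal noise of 1 size for all constructs, without the unread and the dominant barcodes of the data. These rates may therefore not hold for the real libraries. Without any effect the permutation tests passed an unadjusted 0.05 in between 0% and 5.75% of simulations. The simulated values were independent, unlike the differences of mixed arrays that share homotypic arrays. They therefore could not check the error rate of the pair tests. Alternatives covered scaling (library totals, constructs without a motif, median centring), DESeq2 1.42.0, read and barcode minimums, medians over barcodes, pseudocounts of 0.1 and 2, replicate numbers as a block, each replicate left out, and other expectations for mixed arrays. Counting distinct barcodes in place of reads was not possible for the episomal libraries, where each listed barcode has reads in each library; for the integrated library the share of barcodes with mRNA was used.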

Results

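The series asked how the number, spacing, combination and flanking sequence of transcription factor motifs set the activity of artificial enhancers in MEC1 cells. Arrays held 1 to 5 copies of 1 motif, or a mixture of a pair of motifs, in 3 flanking contexts, with 5 bp or 10 bp between neighbouring motifs. The 8 motifs were those of CTCF, FOXO, IRF, MEF2, MYC, NFKB, PU1 and RUNX3. CTCF is known for chromatin loops and insulation, NFKB and IRF for immune and inflammatory transcription, and PU1 and RUNX3 for blood cell development. The 5 bp episomal library gave 4206555 plasmid DNA reads and 4389405 and 3850658 mRNA reads, and the 10 bp library 4563359 plasmid DNA reads and 4410738 and 4356282 mRNA reads. The integrated 5 bp library was given as RPM for 16189 barcodes. That table gives no read totals, and 63.4% of its barcodes had no mRNA in any of the 3 replicates.

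With 5 bp spacers NFKB arrays were the most active of the 8 motifs and CTCF arrays the least active. Homotypic NFKB arrays lay 2.76 ± 0.02 log2 units (SD, n = 2) above the constructs without a motif, a 6.77-fold difference, with an adjusted permutation p of 6e-05 against the other motifs. CTCF arrays lay at -1.59 ± 0.0023, which is 3.00-fold lower, with the same adjusted p of 6e-05. The SD covers only the 2 mRNA libraries, which share 1 plasmid DNA library. The 3 constructs without a motif ranged in activity from -1.55 to -1.12. The other motifs lay between -0.43 for PU1 and 0.57 for IRF and did not pass the test by motif label, except RUNX3 (-0.40) with at least 20 plasmid reads per barcode (adjusted p = 0.046) or 20 barcodes per construct (0.0442). By edgeR 13 of 15 NFKB arrays were higher in mRNA than in plasmid DNA, and all 11 homotypic CTCF arrays were lower. All 77 constructs holding a CTCF motif, alone or mixed, were lower (76 when scaled on the constructs without a motif). Of the CTCF barcodes with at least 50 plasmid reads, 25.6% still had 1 mRNA read, the lowest number that a listed barcode has.

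Of the 442 designs tested at 5 bp, 179 were higher and 219 lower in mRNA than in plasmid DNA (edgeR, adjusted p under 0.05). This split follows the scaling, with 100 higher and 309 lower by library totals and 290 higher and 115 lower when scaled on the constructs without a motif. Against TMM, these scalings moved the median log2 ratio by -0.67 and 0.75. Homotypic FOXO, IRF and MYC arrays changed sign with it, for instance from -0.26 to 0.49 for FOXO. The most active designs mixed FOXO with NFKB or held NFKB alone. The alternating array of 3 FOXO and 2 NFKB motifs reached a log2 ratio of 3.91 (SE 0.07) in context 1 and 3.30 (SE 0.07) in context 2. The array of 5 NFKB motifs reached 3.32 (SE 0.09) in context 1 and 2.98 (SE 0.09) in context 3, and the alternating array of 4 FOXO and NFKB motifs in context 2 reached 2.99 (SE 0.06). The largest decreases were -2.90 (SE 0.18) and -2.55 (SE 0.26) for alternating MEF2 and CTCF arrays, -2.71 (SE 0.11) for 3 CTCF motifs, -2.52 (SE 0.13) for NFKB between CTCF motifs and -2.48 (SE 0.21) for 5 MEF2 motifs. Of these decreases, 3 rest on 17 or fewer barcodes.

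With 10 bp spacers IRF arrays were the most active, at 1.59 ± 0.11 log2 units (SD, n = 2) over the constructs without a motif (adjusted permutation p = 6e-05). NFKB arrays lay 0.54 ± 0.12 above them (adjusted permutation p = 0.0061). CTCF arrays were again lowest at -2.23 ± 0.0053 (adjusted permutation p = 6e-05), followed by MYC at -1.21 (0.0161) and PU1 at -1.13 (0.0481). These p-values compare each motif with the other motifs, not with the constructs without a motif. The 3 constructs without a motif ranged in activity from -0.87 to -0.31. The PU1 call was lost with other minimums of reads or barcodes or without mRNA replicate 1 (adjusted p from 0.0513 to 0.0639), at differences from the mean of all motifs between -0.75 and -0.70, beside -0.73 as tested. By edgeR all 15 IRF arrays were higher in mRNA, and 76 of 77 constructs holding CTCF were lower. Of the 442 designs 202 were higher and 215 lower, against 138 and 276 by library totals. That scaling moved the median log2 ratio by -0.55 and took homotypic NFKB arrays from 0.48 to -0.08. NFKB flanking an IRF motif in context 3 was the most active design at a log2 ratio of 2.65 (SE 0.05), followed by NFKB with IRF in context 2 at 2.49, NFKB flanking RUNX3 in context 3 at 2.39, and 2 and 3 IRF motifs at 2.32 in contexts 1 and 3. The 5 largest decreases, from -2.97 to -3.40, each held CTCF.

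Between the spacers, IRF and RUNX3 arrays were more active with 10 bp and NFKB and MYC arrays with 5 bp. Relative to TMM scaling the mean log2 difference (10 bp minus 5 bp) over homotypic IRF arrays was 1.72, with 14 of 15 higher, and over RUNX3 arrays 0.98, with 14 of 15 higher (adjusted permutation p = 0.0004 for each). NFKB arrays differed by -1.52, with 13 of 15 lower (adjusted permutation p = 0.0059), and MYC arrays by -0.92, with 13 of 15 lower (adjusted permutation p = 0.0011). Scaled on the constructs without a motif, these means became 1.01, 0.27, -2.23 and -1.63, keeping their signs, and only 8 RUNX3 arrays then passed as higher. MEF2 arrays turned from 0.47 to -0.23 and CTCF arrays from 0.05 to -0.66, and PU1 arrays stood at 0.11 by library totals and at -0.71. FOXO arrays differed by -0.39 and did not pass as a group (adjusted permutation p = 0.0656), though 12 of 15 were lower by edgeR, and scaled on the constructs without a motif they differed by -1.10 with 14 of 15 lower. The 3 constructs without a motif, which hold no spacer between motifs, were themselves 0.69 higher in the 10 bp library. The largest rises were IRF arrays of 1, 2, 3 and 5 motifs in context 3, from 2.38 to 2.58, and the alternating FOXO and IRF array of 5 motifs in context 3 at 2.30. The largest falls were -3.13 for 3 NFKB motifs in context 3, -2.90 for 5 in context 1, -2.90 and -2.88 for 4 in contexts 3 and 1, and -2.57 for MYC between NFKB motifs in context 3.

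Of 442 designs, 159 were higher and 182 lower with 10 bp spacers (edgeR, adjusted p under 0.05), against 66 and 306 when scaled on the constructs without a motif. That scaling moved the median difference by -0.71. Each spacer was its own plasmid pool and set of transfections, so spacing and pool cannot be separated in this comparison. Arrays of 1 motif, which have no neighbour to be spaced from, also differed: 11 of 24 were higher and 5 lower in the 10 bp library (5 and 14 when scaled on the constructs without a motif). By TMM scaling, those in context 3 were 1.23 higher on average (SD 0.86 over 8 arrays, exact sign-flip p = 0.00781), those in context 1 were 0.47 higher (SD 0.41, exact p = 0.00781), and those in context 2 were lower, at -0.28 (SD 0.23, exact p = 0.00781). The single construct without a motif in each context differed by 0.58, 0.81 and 0.69 in contexts 1 to 3.

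Activity rose with motif number for NFKB with 5 bp spacers, and fell for several other motifs. NFKB arrays gained 0.67 ± 0.02 log2 units per added copy (SD, n = 2; adjusted permutation p = 0.00024), from -0.38 with 1 copy to 2.48 with 5. MEF2 lost -0.51 per copy, RUNX3 -0.40 and PU1 -0.39 (adjusted permutation p = 0.00192, 0.00054 and 0.00032). The MEF2 call at 5 bp was lost without arrays of 5 copies (-0.43, adjusted p = 0.0668) and with at least 20 plasmid reads per barcode (-0.48, 0.105) or 20 barcodes per construct (-0.39, 0.146). With 10 bp spacers the NFKB slope was -0.17 and did not pass, whereas MEF2 (-0.45), PU1 (-0.42), MYC (-0.38) and FOXO (-0.23) fell with copy number. Without arrays of 1 copy the 10 bp slopes of PU1 (-0.09, adjusted p = 0.567) and FOXO (-0.10, adjusted p = 0.269) no longer passed, and that of RUNX3 did (-0.48, adjusted p = 0.0211). IRF activity at 10 bp rose from 0.40 with 1 copy to 1.51 with 2 and stood at 0.79 with 5, with a slope of 0.03 that did not pass. CTCF arrays stayed between -2.97 and -2.84 at 5 bp for all copy numbers measured, with a slope of -0.04 ± 0.04 that did not pass.

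**Figure D1:**
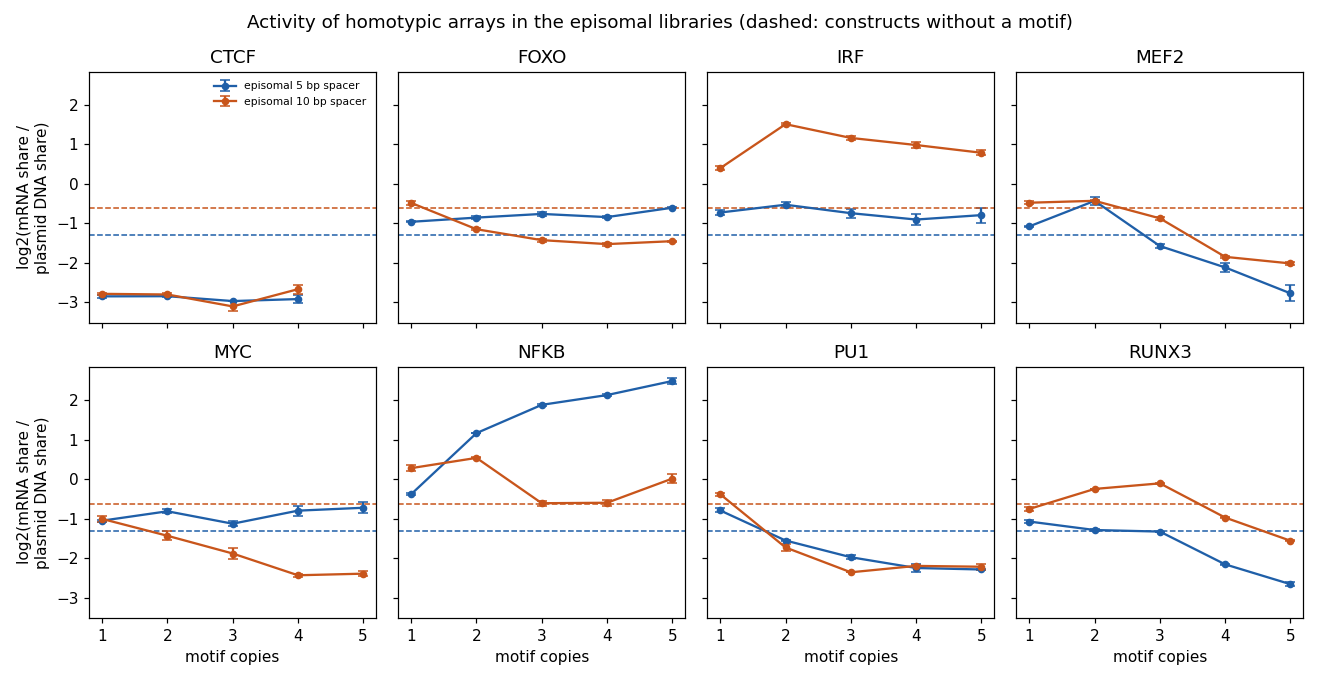
Activity (log2 of mRNA share over plasmid DNA share, y axis) of homotypic arrays against the number of motif copies (x axis) in the 5 bp and 10 bp episomal libraries, 1 panel per motif. Points are means over the contexts present, bars the SD between 2 mRNA replicates and dashed lines the constructs without a motif; NFKB arrays at 5 bp run from -0.38 to 2.48, and CTCF arrays at 5 bp lie between -2.97 and -2.84.

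Mixing motifs gave more activity than the copy-weighted mean of the homotypic arrays for many pairs with FOXO or MEF2, and at 5 bp less for 6 of the 7 pairs with CTCF. In that library, 12 of 28 pairs lay above this expectation and 8 below it, by sign flips over constructs that share homotypic arrays. The highest median departures were 1.82 ± 0.08 for MEF2 with PU1 (SD, n = 2; 20 of 20 constructs above; adjusted permutation p = 0.00014), 1.37 for FOXO with MEF2, 1.23 for MEF2 with NFKB and for FOXO with NFKB, and 1.22 for FOXO with RUNX3. Every construct of these pairs lay above its expectation. CTCF with NFKB departed by -1.87 (0 of 12 above; adjusted permutation p = 0.00242), and CTCF with FOXO (-0.92), IRF (-0.91), RUNX3 (-0.67) and MYC (-0.66) followed. With a sign flip of the median in place of the mean, CTCF with IRF, RUNX3 and MYC did not pass (adjusted p = 0.0719, 0.0719 and 0.119). These pairs hold only 10, 10 and 8 constructs. That test called 0% of simulated true effects with 6 values, so these losses decide little. Against the stronger of the 2 homotypic arrays, FOXO with NFKB and MEF2 with NFKB lay below expectation at 5 bp, at -0.13 and -0.52, and over the 3 libraries 14 pairs were above and 47 below, in place of 30 and 12. That expectation is never below the copy-weighted mean, so more pairs fall below it by construction.

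At 10 bp, 12 pairs lay above and 1 below. FOXO with NFKB led at 1.91 ± 0.0011 (SD, n = 2; 18 of 18 above; adjusted permutation p = 0.000153), then FOXO with IRF (1.13), MEF2 with NFKB (1.11), NFKB with PU1 (1.07) and FOXO with RUNX3 (1.00). Against the stronger homotypic array, FOXO with IRF stood at -0.56 and NFKB with PU1 at -0.14, and NFKB with PU1 did not pass with a sign flip of the median (adjusted permutation p = 0.119). All 9 constructs of NFKB with PU1 lay above the copy-weighted mean, and the sign flip of the median called 0% of simulated true effects with 6 values. CTCF with FOXO was the pair below, at -0.99. CTCF with IRF (-1.87), RUNX3 (-1.06) and MYC (-0.78) rest on 6 constructs each, whose exact p of 0.0313 is the smallest they can give and did not pass after adjustment (0.0547), and CTCF with NFKB (-0.85) did not pass (adjusted permutation p = 0.0776). These 4 pairs passed against the stronger homotypic array (adjusted permutation p from 0.00448 to 0.0437) and against the linear mean (0.0162 to 0.0495). Both expectations lie at or above the copy-weighted mean of the log2 activities. An array that only averages its motifs falls below them, so these calls do not show a negative departure from that mean. Motif order was compared in arrays with 1 copy of each motif of a pair, averaged over partners and contexts. Swapping which motif came first changed this mean past the threshold for 1 of 24 combinations of motif and library. It was IRF at 10 bp, at -0.25 when first (lower in 16 of 21 matched designs, adjusted permutation p = 0.0209). Opposite effects with different partners cancel in such a mean, and each matched pair enters the test of both its motifs. Order within single pairs was not tested.

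**Figure D2:**
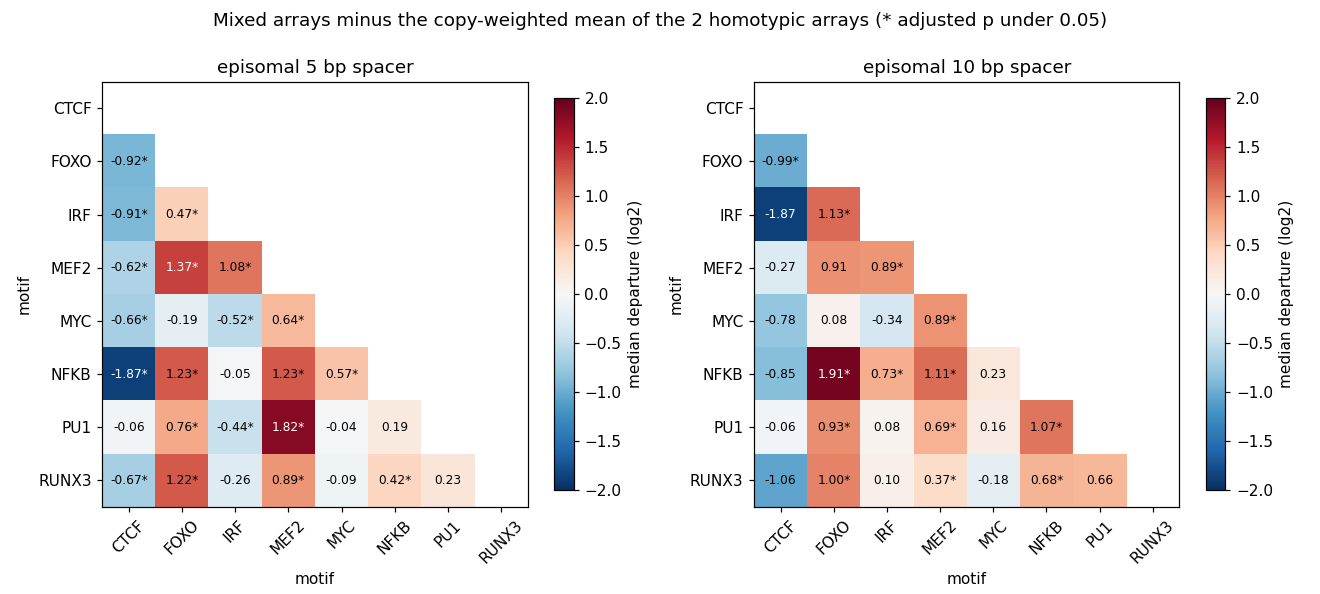
Median departure (log2, colour and number) of mixed arrays from the copy-weighted mean of the 2 homotypic arrays, for each pair of motifs (both axes), at 5 bp (left) and 10 bp (right). An asterisk marks an adjusted p under 0.05; MEF2 with PU1 stands highest at 5 bp (1.82) and FOXO with NFKB at 10 bp (1.91), and pairs with CTCF run from -0.06 (with PU1, both libraries) to -1.87.

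The flanking context also changed the activity of matched designs. At 10 bp, context 3 exceeded context 1 by 0.28 ± 0.02 (SD, n = 2; 98 of 146 designs higher) and context 2 by 0.44 ± 0.0060 (119 of 146), each with an adjusted permutation p of 4.5e-05. Context 2 was lower than context 1 at -0.17 ± 0.01 (49 of 148 higher; adjusted permutation p = 0.0016). At 5 bp the differences were -0.07 (2 minus 1), -0.14 (3 minus 1) and -0.07 (3 minus 2), with adjusted permutation p of 0.0332, 0.00021 and 0.0359. Without a plasmid read minimum 2 minus 1 (-0.06) and 3 minus 2 (-0.07) were lost (adjusted p = 0.0542 for each), and 3 minus 2 also without mRNA replicate 1 (-0.05, adjusted p = 0.17). On homotypic arrays alone, only context 3 minus 2 at 10 bp passed in any library. In the integrated library context 3 minus 2 was -0.46 ± 0.23 (SD, n = 3; adjusted permutation p = 0.0233), and it did not pass without mRNA replicate 2 (-0.39, adjusted p = 0.0769) or with at least 20 barcodes per construct (-0.29, adjusted p = 0.208), where context 3 minus 1 did (-0.45, adjusted p = 0.0467).

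After integration into the genome, IRF and NFKB arrays were the most active and RUNX3 and MEF2 arrays the least. Relative to constructs without a motif, IRF arrays lay at 2.65 ± 0.20 (SD, n = 3; adjusted permutation p = 9.6e-05) and NFKB arrays at 1.59 ± 0.41 (0.00896), against -2.38 ± 1.22 for MEF2 (0.00654) and -2.94 ± 0.20 for RUNX3 (0.00144). The p-values again compare each motif with the other motifs, not with the constructs without a motif. Those 3 reference constructs ranged from -3.77 to 0.75 among themselves. The MEF2 call was lost with at least 20 plasmid reads per barcode (adjusted p = 0.0784) and the NFKB call with at least 20 barcodes per construct (adjusted p = 0.128), and the RUNX3 mean of -4.28 holds 2 arrays listed at 0 mRNA, without which it was -3.29. CTCF arrays stood at -1.23 ± 0.85 and did not pass by motif label, except with at least 20 plasmid reads per barcode (adjusted p = 0.046). By limma 69 of 92 constructs holding CTCF were lower in mRNA than in genomic DNA and 5 higher, beside 287 lower of all 513, and centred on constructs without a motif 26 of the 92 were lower and 6 higher.

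Integrated IRF and NFKB arrays rose with motif number, by 0.99 ± 0.06 and 0.84 ± 0.20 log2 units per copy (SD, n = 3; adjusted permutation p = 0.0014 and 0.0138), and MYC arrays fell at -1.21 ± 0.24 (0.0389). Without arrays of 5 copies the IRF slope was 0.94 (adjusted p = 0.0103), whereas NFKB (0.58, adjusted p = 0.248) and MYC (-0.73, 0.413) no longer passed. Without arrays of 1 copy NFKB (0.77) and MYC (-1.32) did not pass either (adjusted p = 0.16 for each), and without mRNA replicate 1 their adjusted p were 0.0538 and 0.0501. With at least 20 barcodes per construct fewer arrays remained and none of these slopes passed, at 1.25 for IRF, 1.23 for NFKB and -0.91 for MYC. The share of integrated barcodes with any mRNA, where each barcode counts once, went from 37.1% ± 4.45 (SD, n = 3) with 1 IRF copy to 76.0% ± 8.00 with 4. With 5 IRF copies it was 100%, from 3 barcodes of 1 construct. NFKB arrays went from 18.9% ± 5.56 to 73.3% ± 11.5 with 5 copies (15 barcodes), PU1 arrays stood at 40.3% ± 1.39 with 1 copy, and RUNX3 arrays went from 9.79% ± 4.62 to 3.23% with 5. Constructs without a motif stood at 9.49% ± 3.08 and CTCF arrays between 8.33% and 10.4%. MEF2 arrays stood between 9.52% and 11.4%, so by this share they were not below the constructs without a motif. Slopes of the share were fitted to the share per construct, so the IRF construct with 3 barcodes weighs as much as the others. The share rose for IRF by 12.9 points per copy and for NFKB by 12.0 (adjusted permutation p = 0.0143 and 0.00424), and changed for RUNX3 by -1.66 (0.0287). For MYC it changed by -1.29 points per copy and did not pass (adjusted permutation p = 0.205).

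**Figure D3:**
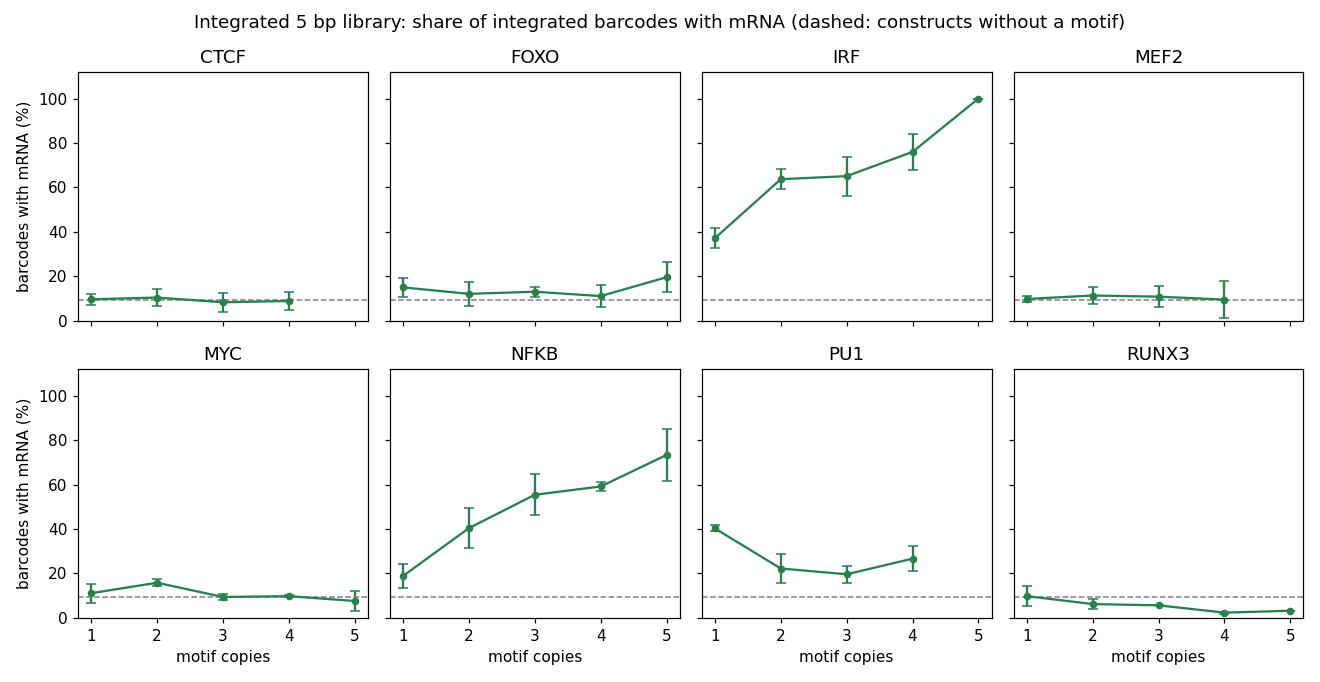
Percentage of integrated barcodes with mRNA (y axis) against the number of motif copies (x axis) for homotypic 5 bp arrays, 1 panel per motif. Points are means and bars the SD over 3 mRNA replicates, and the dashed line marks the constructs without a motif (9.49%); IRF arrays run from 37.1% to 100% and NFKB arrays from 18.9% to 73.3%.

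Of 513 integrated constructs, 69 were higher and 287 lower in mRNA than in genomic DNA (limma, adjusted p under 0.05). The split reversed to 175 higher and 83 lower after median centring and to 147 and 94 when centred on constructs without a motif. The barcodes with most mRNA, 1 each in IRF with PU1 in context 2 and in 3 MYC motifs in context 3, held between 35.0% and 42.2% of the listed mRNA per replicate. Without those 2 barcodes, 104 constructs were higher and 167 lower, and the log2 ratio of the MYC array went from 4.28 (SE 0.15) to 0.20. IRF with PU1 in context 2 stood at 7.93 (SE 0.24, 20 barcodes) and without those 2 barcodes, which also rescales the mRNA totals (5 IRF motifs then stood at 4.92), at 0.90 (adjusted p = 0.0213). Further increases were 5 IRF motifs in context 2 at 4.22 (3 barcodes), 5 NFKB motifs in context 1 at 2.97 (5 barcodes) and MEF2 with IRF in context 2 at 2.87 (15 barcodes). Among the largest decreases, 4 RUNX3 motifs in context 3, 5 RUNX3 motifs in context 1 and RUNX3 among 3 MEF2 motifs in context 3 were listed at 0 mRNA in all 3 replicates. The array of 4 RUNX3 motifs in context 2 had mRNA for 2.70% of its 37 barcodes and the alternating FOXO and MYC array of 5 in context 3 for 3.03% of 11. Among mixed arrays 6 of 28 pairs lay above expectation and 3 below, led by MEF2 with PU1 at 2.42 ± 0.47 (SD, n = 3; 14 of 14 above; adjusted permutation p = 0.000887). FOXO with MEF2 (1.45) and FOXO with PU1 (1.28) also passed, but not against the stronger homotypic array (0.69 and 0.77). The pairs below were CTCF with IRF at -1.42 (adjusted permutation p = 0.0128), a call lost without mRNA replicate 2 (-0.67, adjusted p = 0.168) and with a sign flip of the median (0.0719), and, named after their values were seen and not run under the alternatives, IRF with NFKB at -1.21 (1 of 12 above, adjusted permutation p = 0.0046) and IRF with MYC at -1.09 (1 of 12, 0.0037). With at least 20 barcodes per construct MEF2 with PU1 (2.40), FOXO with MEF2 (1.76), FOXO with PU1 (0.85) and CTCF with IRF (-1.64) did not pass on fewer constructs (adjusted p from 0.0625 to 0.184). FOXO with RUNX3 (2.08), MEF2 with NFKB (1.52, and -1.47 against the stronger homotypic array), CTCF with NFKB (-1.92), CTCF with MYC (-1.67), CTCF with MEF2 (-1.40) and FOXO with MYC (-1.31) did not pass. CTCF with NFKB passed without mRNA replicate 1 (-2.05, adjusted p = 0.0474) or 3 (-1.60, 0.0177), CTCF with MEF2 without replicate 3 (-2.47, 0.0097), and both against the stronger homotypic array or the linear mean, as FOXO with MYC did against the stronger array. The stronger array and the linear mean are never below the copy-weighted mean, so passing below them does not show a negative departure from it.

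Across the 513 constructs shared by the 5 bp episomal and integrated tables, activity correlated with a Pearson r of 0.40 and a Spearman rho of 0.43 (permutation p = 1e-05 for each, the smallest possible). Within copy number 1 the Spearman rho was 0.25 and did not pass (permutation p = 0.237, 24 constructs), within copy numbers 2 to 5 it was 0.40, 0.46, 0.50 and 0.58, and within contexts 1 to 3 it was 0.52, 0.35 and 0.41. Without constructs holding CTCF it was 0.35. With the share of barcodes with mRNA in place of the integrated ratio it was 0.56. Both settings were chosen after the data were seen. These correlations run across constructs, which are not independent replicates. Between the 5 bp and 10 bp episomal libraries the rho over 442 designs was 0.73, and 0.57 without CTCF.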

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

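The tests on scaling, on arrays of 1 copy, on CTCF after integration, on the share of barcodes with mRNA and on other splits of the samples were chosen after the results were seen. The tests with 50 plasmid reads and with the median over barcodes were set before theirs.

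The difference between spacers was tested directly and stood out for 159 designs that were higher and 182 that were lower with 10 bp (66 and 306 when scaled on the constructs without a motif). The largest differences were 2.58, 2.38, 2.38 and 2.38 for 1, 3, 5 and 2 IRF motifs and 2.30 for alternating FOXO and IRF motifs, all in context 3. On the other side were -3.13, -2.90, -2.90 and -2.88 for NFKB arrays of 3, 5, 4 and 4 motifs and -2.57 for MYC between NFKB motifs.

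NFKB arrays favoured 5 bp and IRF arrays 10 bp under each of 3 scalings, where the IRF value nearest to 0 was 1.01, and the gap of IRF minus NFKB was 3.22 with the median over barcodes, which argues against scaling and against a few dominant barcodes as the whole cause. A difference between the pools or transfections stays open, because arrays of 1 copy, which have no spacing, gave -0.023 for NFKB (SD 1.38 over contexts) and 0.44 for IRF (SD 1.41) relative to constructs without a motif. A preference of the bound factors for a certain spacing may also account for it, and no biological explanation was tested.

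Averaged over contexts, CTCF arrays were similarly low at every copy number measured in both episomal libraries. Single arrays ranged in activity from -3.26 to -2.67 at 5 bp but from -3.64 to -1.69 at 10 bp, so the 10 bp means hold uneven arrays. With at least 20 barcodes per construct the 10 bp slope was -0.23 (adjusted permutation p = 0.0218). The tables list only barcodes read in every library, which sets a floor for weak arrays. With at least 50 plasmid reads per barcode the lower of the CTCF slopes was -0.15 (SD 0.12), above the bound of -0.2 set beforehand for an absent floor; that bound was a poor one, because 25.6% (5 bp) and 24.2% (10 bp) of these barcodes still had 1 mRNA read and the mean level moved down to -3.42 and -3.23. A condition that under 5% of barcodes sit at 1 read was added after this was seen, and the floor stays open. Loss of CTCF transcripts during reverse transcription or amplification may also contribute. Integrated CTCF arrays stood at -1.23 (SD 0.85) over constructs without a motif, too imprecise to argue against such a loss. A low value could not separate the loss from a biological effect of CTCF, which was not tested. The share of integrated barcodes with mRNA was between 8.33% and 10.4% for CTCF arrays, beside 9.49% ± 3.08 for constructs without a motif.

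Copy number slopes ran in opposite directions in all replicates of a pair of libraries for several motifs, and these differences were not tested. For 10 bp minus 5 bp they were -0.30 for FOXO, 0.076 for IRF, -0.44 for MYC and -0.84 for NFKB. For integrated minus episomal 5 bp they were -0.29 for FOXO, 1.04 for IRF and -1.28 for MYC. The 5 bp episomal slopes of FOXO, IRF and MYC did not pass, nor did the 10 bp slopes of IRF and NFKB or the integrated FOXO slope. Each listed comparison thus holds a slope that was not told apart from 0. The 10 bp IRF slope of 0.03 turned to -0.24 without arrays of 1 copy.

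IRF and NFKB arrays rose with copy number after integration. A few barcodes with very high mRNA are argued against as the cause, since the share of barcodes with mRNA per construct rose too (the larger adjusted permutation p of both motifs was 0.0143). Within a construct each barcode counts once in this share. Constructs weigh equally in its slope, including the 1 IRF construct of 5 copies with 3 barcodes, and it was not run without that construct. Pooled over barcodes, the IRF share was 37.1%, 63.7%, 65.1% and 76.0% at 1 to 4 copies. The NFKB slope did not pass without arrays of 5 copies (0.58) or of 1 copy (0.77), though the share of barcodes with mRNA was 18.9%, 40.4%, 55.4% and 59.1% at 1 to 4 copies, and the IRF slope passed without either (0.94 and 0.97). With at least 20 barcodes per construct the slopes stood at 1.25 (IRF) and 1.23 (NFKB) and did not pass on the fewer arrays left. What stays open is whether the factors themselves may act differently on integrated DNA, which was not tested. Of the 10 splits of the 6 integrated samples into 3 and 3, 1 (the real one) gave 356 constructs past the threshold and the highest other gave 0; with 10 splits no share under 0.05 can be reached.

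Barcodes without a construct name, which no comparison used, showed activity above the constructs without a motif, at 1.10 log2 units in the 5 bp library and 0.48 in the 10 bp library. In mRNA replicate 1 they stood at 1.09 and 0.42, against 1.28 and 0.55 for named barcodes.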

How the results depend on the processing

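Centring on constructs without a motif (for the integrated library), leaving out the 2 barcodes with most mRNA, the share of barcodes with mRNA, leaving out CTCF constructs and the sign flip of the median were chosen after seeing the data. Of 226 summary values under alternatives, 205 held and 21 moved. Counts held if they kept within 1.5 times of the reported count, and correlations if they kept their sign and side of the threshold. Counts over the 3 libraries can change little where a setting touches only 1 of them. Of 1218 values of single motifs, slopes, pairs and constructs, 1121 kept their direction and side of the threshold, 47 lost the call, 26 gained it and 24 reversed. The constructs were picked from these data for their large changes, so their calls were likely to hold. Of their values 125 of 125 stayed the same at 5 bp, 128 of 128 at 10 bp, 120 of 120 between spacers and 143 of 147 after integration. Among motif levels 137 of 152 values stayed the same, and among slopes 178 of 200. Dropping the barcode minimum added no episomal design, so that setting could change nothing there. For each change the cause was not tested, except that leaving out arrays or thin constructs leaves fewer values.

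By library totals 100 designs were higher at 5 bp. Centring on constructs without a motif gave 290 higher and 115 lower at 5 bp, 66 and 306 between spacers, and 147 and 94 after integration. For the integrated library the median over barcodes gave 21 higher and 435 lower, median centring 175 and 83, and leaving out the 2 barcodes 104 and 167. With at least 20 barcodes per construct 1 slope rose past the threshold in place of 3. Context differences below 0 numbered 3 without a plasmid read minimum and 0 on homotypic arrays (1 above 0), in place of 5 and 2. Pairs below expectation numbered 7 with the sign flip of the median, 47 against the stronger homotypic array (14 above) and 26 against the linear mean, in place of 12 (30 above). The stronger array and the linear mean are never below the copy-weighted mean, which raises these counts.

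No pairing by replicate number was seen: deviations of same-numbered samples correlated at 0.05 in the episomal libraries and at -0.02, 0.05 and -0.03 in the integrated one. Such correlations cannot show that RNA and genomic DNA extracted jointly are unpaired. With the replicate number as a block, 178 and 217 designs were higher and lower at 5 bp, 203 and 209 at 10 bp, 160 and 185 between spacers, and 50 and 242 after integration. Without each replicate in turn the counts ran from 174 to 181 and 210 to 223 at 5 bp, and from 49 to 72 and 198 to 297 after integration.

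Reversals lay mostly in the integrated library. Motif levels here are differences from the mean of all motifs at the same copy number and context, as the test uses them (0.27 for MYC and 0.11 for PU1 as reported). The median over barcodes lies at 0 mRNA for most integrated constructs, so most of its values are set by that floor and do not bear on stability: it gave -2.86 for IRF with PU1 in context 2 (53.3% of barcodes with mRNA), -5.41 for 3 MYC motifs in context 3, -5.70 for MEF2 with IRF in context 2, levels of -1.25 (MYC) and -0.45 (PU1), a FOXO slope of 0.25, a context 2 minus 1 difference of -0.16, and pair departures of 0.10 (CTCF with MEF2), 0.064 (FOXO with MYC) and -0.037 (MEF2 with NFKB). Without each mRNA replicate the PU1 level ran from -0.29 to 0.45, and the MYC level was -0.0055 without the 2 barcodes. With at least 20 barcodes the MYC level was 1.51 (now past the threshold), the MEF2 slope was 0.095 and context 2 minus 1 was -0.066. On homotypic arrays context 3 minus 1 was 0.23. At 10 bp the CTCF slope ran from -0.048 to 0.013 without each mRNA replicate and was 0.034 without arrays of 1 copy, where the IRF slope was -0.24. Against the stronger homotypic array, FOXO with NFKB (-0.13) and MEF2 with NFKB (-0.52) at 5 bp, FOXO with IRF (-0.56) and NFKB with PU1 (-0.14) at 10 bp, and integrated MEF2 with NFKB (-1.47) reversed, the last also against the linear mean (-0.56).

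Depth limits single barcodes in the episomal libraries, with a median of 4 to 7 reads per library. Of the integrated barcodes 63.4% had no mRNA, while those with mRNA had a median of 40.9 to 63.8 RPM; whether depth is the reason was not tested. Counting distinct barcodes was not run for the episomal libraries, where each listed barcode has reads in every library, nor DESeq2 or voom on the integrated RPM, which are not counts.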

Other observations

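The contrasts of arrays of 1 copy by context and of PU1 copies were noticed and tested after the data were seen. In context 3 single copies of IRF (2.58), MEF2 (1.90), NFKB (1.73) FOXO (1.63), PU1 (0.88) and RUNX3 (0.77) were higher in the 10 bp than in the 5 bp library (edgeR), where the construct without a motif differed by 0.69, whereas single copies of CTCF (0.18) and MYC (0.18) did not pass (edgeR, adjusted p = 0.178 and 0.0546). In context 2 the same motifs stood between -0.77 for NFKB and -0.05 for CTCF. In context 1 NFKB (1.05), IRF (0.94), PU1 (0.70), RUNX3 (0.66) and MYC (0.22) were higher, where the construct without a motif differed by 0.58. Where the lone motif lies in each library is not given in the sources used here.

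Of the integrated barcodes, 65.6% were also listed in the 5 bp episomal table, against 2.93% that barcode numbers alone would give, and 2.13% in the 10 bp table, against 2.22%. Of the shared barcodes with a name in both, 99.0% carried the same construct name.

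A PU1 motif on its own had mRNA for 40.3% of integrated barcodes, against 22.2%, 19.6% and 26.7% with 2, 3 and 4 copies and 9.49% for constructs without a motif. The slope of this share, taken per construct, over PU1 copies was -5.95 points per copy and did not pass (adjusted permutation p = 0.196).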
